A study of Mus musculus with 6 samples.

How the data were processed

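The series holds 6 ATAC-seq libraries of sorted microglia, 3 labelled cKO and 3 labelled cWT. Grouping followed the sample titles. The files used are 2 peak lists of the whole series, 1 per genotype, named as specific to that genotype; each holds positions, a name, a score, a signal, a p-value and an adjusted p-value per peak, without a header. Per the submitters' processing notes, Bowtie2 2.4.4, MACS2 2.2.7.1 and HOMER 4.11 were used with the mouse builds GRCm38 and mm10; the step each tool did, how replicates were combined, any shift of reads for the transposase, and how specific peaks were chosen are not given in the sources used here. Because the lists hold no values per library, the number of reads behind a peak and the depth per sample are unknown. A deeper or cleaner set of libraries in 1 genotype can lengthen its list, and this cannot be corrected from the lists.

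The score that the authors deposited for each peak equals -125 times log2 of the peak's p-value, rounded down, in all 8615 cKO and 3490 cWT peaks. The signal the authors deposited has no stated scale and was used only to describe peaks within a list. The columns have no header, and their reading as a signal, a p-value and an adjusted p-value rests on their layout and values. What the p-value the authors deposited tests is not given in the sources used here, so a limit set on it in both lists may not mean the same in each. The adjusted p-value they deposited has the form of a Benjamini-Hochberg adjustment with most peaks on 1 plateau. Peaks named primary have p-values up to 0.223 in cKO and 0.226 in cWT, and those named secondary lie above. The number in a peak's name rises with position along each chromosome, so it was read as the peak's place in the genotype's full called list; the last number, 33339 in cKO and 28747 in cWT, is a lower bound of that list's length. The 24724 and 25257 numbered peaks outside the lists were not used here.

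Gene positions came from a RefSeq gene table of the same assembly, GRCm38.p6, with 21887 protein-coding genes. The table gives each gene's span without strand, exons or sequence. Planned promoter results therefore use either end of a coding gene within 1000 bp of the peak's midpoint, called a gene end, and exon, intron and UTR classes were replaced by gene interior and intergenic. The 30 fixed motifs, GC content and repeat content need a genome sequence and were not tested. Each peak was assigned to the coding gene with the nearest end, up to 100 kb; 11013 of 12105 peaks (91.0%) were assigned, to 6118 genes. A nearby gene is not shown to be the gene a peak regulates.

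The share of cKO peaks has an exact (Clopper-Pearson) 95% interval. Overlaps were found with bedtools 2.31.1 at a minimum of 1 bp. Region classes, chromosomes and gene lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, with 2000 block bootstrap draws over 10 Mb blocks for region classes, and distances by a permutation test of 100000 resamples. Coverage of 19 gene lists, fixed with 393 entries before the data were examined, was compared with 10000 random lists drawn from the other genes and matched on deciles of territory length, the stretch in which a peak would be assigned to the gene; this is called a permutation test below, since membership is redrawn at random, and 387 of the 388 distinct genes are annotated as coding, Mx1 being a pseudogene there. The balance of single genes with at least 5 peaks was tested by an exact binomial test. Named genes followed a rule fixed in advance: Mir137 and Tmem119; up to 3 genes per list with the most cKO-specific and up to 2 with the most cWT-specific peaks; the 10 genes with the most peaks in each list, since no gene passed; and the 5 highest-scored gene-end peaks of each list. Wwp2 and Zcchc24, and the genes Selplg, Coro1c, Pus10, Cask and Vps13d beside named ones, were chosen after their values were seen. The result of 1 gene that the rule names is not reported here.

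The tests were tried on simulated data. List balance recovered 45.2% of 250 changes of 4 times the odds and called 4 of 700 unchanged lists. List coverage recovered 49.2% of 250 changes of 3 times the peaks and called 6 of 700. In the coverage simulation peaks fell on genes in proportion to territory, so it did not check for a preference of microglial peaks for microglial genes. Alternatives covered the score, the p-value, the overlap rule, the window and gene set, the assignment, the merging of peaks within 500 bp and the matching of random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.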

Results

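Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in microglia sorted from the brains of C57BL/6J mice aged 8 weeks. Microglia are the resident macrophages of the brain. Both genotypes carried Tmem119-CreERT2, a tamoxifen-inducible recombinase expressed from the microglial gene Tmem119. The conditional knockout (cKO) also carried floxed alleles of Mir137, the gene of the microRNA miR-137, and the control (cWT) carried intact Mir137. The labels give 3 libraries per genotype, 6 in all, each from about 50000 cells, after 7 days of tamoxifen begun at 7 to 8 weeks of age. The series states n = 4 mice without tying libraries to animals. The values analysed here were 1 list of genotype-specific peaks per genotype, with no values per library, so the spread between replicates could not be measured and the sequencing depth is unknown. Intervals and p-values below compare the 2 lists over peaks and cover counting error only, not the variation between animals; neighbouring peaks are not fully independent. The series asks which regulators become most active when microglia lose miR-137; the lists were compared here by position and nearby genes, and transcription factor motifs were not tested.

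The engineered loci were examined first. No peak of either list lay within 100 kb of Mir137 (mm10 chromosome 3, 118433857 to 118433929). The nearest cKO-specific peak was 1281137 bp away and the nearest cWT-specific peak 994734 bp away, so the lists carry no measure of the deletion itself. Tmem119, a marker of homeostatic microglia, carried a cKO-specific peak at chromosome 5, 113800053 to 113800623, which is 571 bp wide and has its midpoint inside the gene, 58 bp from one end of it. The authors' signal for this peak was 25.1, its p-value 0.206 and its adjusted p 0.976. Along the next part of the chromosome, 2 cKO-specific peaks were assigned to Selplg, the P-selectin ligand gene, and 1 cKO-specific and 1 cWT-specific peak lay within Coro1c, an actin-binding protein gene. The nearest cWT-specific peak was 54135 bp from Tmem119. Both genotypes carry the recombinase allele at this locus.

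The cKO list held 8615 specific peaks and the cWT list 3490, a ratio of 2.47 (exact 95% interval 2.37 to 2.57). The genes with the most cKO-specific peaks were Sh3pxd2a, a podosome scaffold gene, with 12 cKO-specific and 3 cWT-specific peaks, Pip4k2a, a phosphoinositide kinase gene, with 10 and 0, and Rad51b, a DNA repair gene, with 10 and 2. Lrch1 (9 and 0), Pag1 (9 and 2), Rapgef5 (9 and 3), Rreb1 (8 and 0), Aff1 (8 and 1), Cdk6 (8 and 1) and Akap13 (8 and 2) followed. The genes with the most cWT-specific peaks were Plxnc1, a semaphorin receptor gene, with 5 in each list, and Slc9a9, an endosomal sodium-proton exchanger gene, with 4 cKO-specific and 5 cWT-specific peaks. Cped1, Foxp1, Pex13 and Smyd3 had 4 cWT-specific peaks and 0 cKO-specific peaks each. Cyria, Dhrs3, Gm1966 and Man1a2 had 4 cWT-specific peaks and 1 cKO-specific peak each. The Dhrs3 peaks all lay inside the neighbouring gene Vps13d, 1099 to 91175 bp from Dhrs3. A peak counted for a gene here and below is the assigned peak. It can lie up to 100 kb from the gene or inside another gene. Counts per gene here and below take each listed peak separately. Some peaks adjoin with the same signal. At Sh3pxd2a these were 47316707 to 47316958 and 47316959 to 47317289 (both 15.6), and 47405618 to 47405770 and 47405771 to 47405889 (both 15.6). A further pair there was 47446711 to 47447413 and 47447414 to 47447596 (both 23.0). Adjoining peaks also occurred at Rreb1, Lrch1, Akap13, Cped1, Gm1966, Gpr34, Tab2, Cd9, Stmn2 and Ctsl, among others. They may be parts of 1 region, so these counts can overstate the number of separate regions.

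Some of these peaks formed compact blocks. The 4 cWT-specific peaks assigned to Pex13 lay inside the neighbouring gene Pus10, at chromosome 11, 23687966 to 23696132, and were 4 consecutive peaks of the cWT list's numbering. The 5 cKO-specific peaks of Itgam, the gene of the integrin chain CD11b, were consecutive in the cKO numbering over 9.53 kb, from chromosome 7, 128058625 to 128068149. Over wider stretches, 12 of the 19 numbered cKO peaks from the first to the last specific peak of Sh3pxd2a were specific (47263704 to 47461939). For Aff1 it was 8 of 12 (103678277 to 103807111). The share was lower at the others of the 10 genes with the most cKO-specific peaks, from 8 of 21 at Akap13 to 9 of 17 at Rapgef5. Among all numbered cKO peaks 25.8% were specific, but these genes were picked for having many specific peaks. Both ends of such a stretch are also specific by construction. A share above 25.8% here is therefore no sign of clustering. How often random placement gives such blocks was not worked out.

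Peaks at gene ends with the highest authors' score included, in cKO, those of Gga1, a clathrin adaptor gene (chromosome 15, 78876251 to 78876974, p-value 0.00852), and Tbc1d13, a gene of the Rab GTPase-activating protein family (chromosome 2, 30133179 to 30134044, p-value 0.0310). Kctd13, Pik3ap1 and Mrpl20 completed the first 5. In cWT they were led by Kifc1, a kinesin gene (chromosome 17, 33890511 to 33891117, p-value 0.00748), and Mpzl1, a membrane glycoprotein gene (chromosome 1, 165634189 to 165634837, p-value 0.00830), followed by Echs1, Rogdi and Etv5. The midpoints lay 555 bp from an end of Gga1, 119 bp from Tbc1d13, 181 bp from Kifc1 and 28 bp from Mpzl1. What these p-values test is not stated in the headerless lists, so the same limits set on them in both lists below only filter peaks, and may not mean the same in each.

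The excess of cKO-specific peaks was larger among peaks with a lower authors' p-value: 1042 against 215 at p-values up to 0.5, a ratio of 4.85 (4.18 to 5.64), and 243 against 48 among peaks named primary, a ratio of 5.06 (3.70 to 7.05). At p-values up to 0.05 it was 7 against 4, a ratio of 1.75 whose interval of 0.445 to 8.15 includes equal numbers. No peak of either list had an adjusted p under 0.05; the lowest was 0.194 in cKO and 0.231 in cWT, and the median unadjusted p-value was 0.818 and 0.886. The specific peaks were 25.8% of the 33339 peaks numbered in the cKO list and 12.1% of the 28747 numbered in the cWT list.

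**Figure D1:**
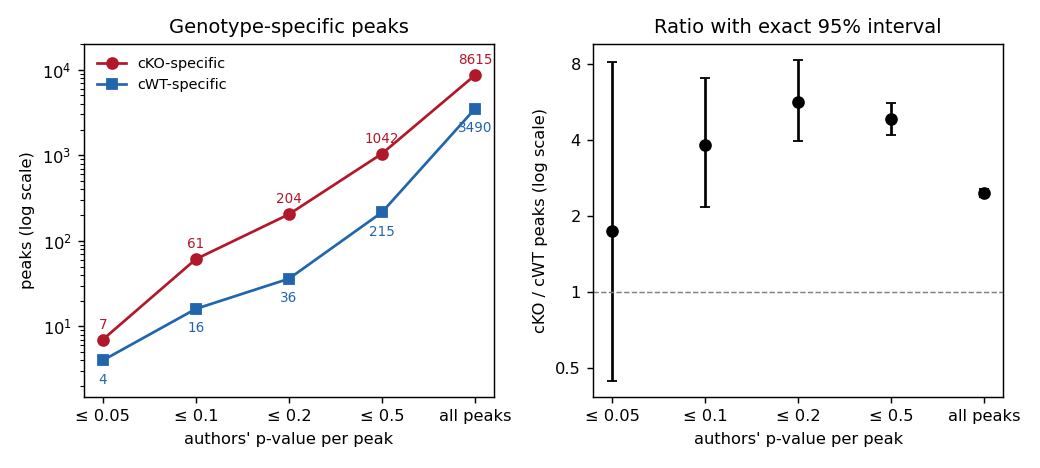
Left, number of genotype-specific peaks (log scale) up to each authors' p-value, for cKO (red circles) and cWT (blue squares); right, the cKO to cWT ratio (log scale) with its exact 95% interval, which covers counting error. The ratio is 2.47 over all peaks and 4.85 at p-values up to 0.5, and its interval includes 1 at p-values up to 0.05.

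Little overlap between the lists follows from their being deposited as genotype-specific, and the rule that set it is not stated. Of the cKO-specific peaks, 184 (2.14%) overlapped 184 cWT-specific peaks (5.27%) by at least 1 bp, with a median overlap of 37.5 bp, and the largest share of either peak covered was 29.96%. At Il6, the interleukin-6 gene, a cKO-specific peak (chromosome 5, 29993658 to 29994129) and a cWT-specific peak (29993445 to 29993712) overlapped in this way. At Irf8, a transcription factor gene of the microglial lineage, a cWT-specific peak (chromosome 8, 120743541 to 120743845) and a cKO-specific peak (120743874 to 120744115) lay side by side inside the gene.

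Genes of homeostatic microglia carried cKO-specific peaks more often than random genes did. Of 24 listed genes, 19 had at least 1 such peak, against a mean of 5.72 in 10000 random lists matched on the length of the gene's territory (adjusted p = 0.0013, permutation, two-sided). Gpr34, a lysophosphatidylserine receptor gene, had 4 cKO-specific and 0 cWT-specific peaks, Entpd1, which encodes the ectonucleotidase CD39, had 4 and 1, Bin1 had 3 and 0, and P2ry12, the ADP receptor gene that guides microglial processes, had 3 and 2. Ltc4s had 1 in each list. The Gpr34 peaks from chromosome X, 13599984 to 13617510, lay inside the neighbouring gene Cask, 5293 to 22551 bp from Gpr34. In the cWT list 7 of the 24 genes had a peak, against a random mean of 2.95 (permutation, adjusted p = 0.156). The random lists here and below were drawn from all other coding genes, whether or not these are open in microglia. The unlisted peaks were not used, so the test cannot separate genotype-specific peaks from microglial peaks in general.

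The same test passed in the cKO list for 8 other gene lists. Among phagocytosis and complement genes, 15 of 23 had a cKO-specific peak (random mean 5.50, permutation, adjusted p = 0.0013), with 5 cKO-specific and 1 cWT-specific peaks at Itgam, 3 and 0 at Itgb2, which encodes its partner chain CD18, 3 and 0 at the scavenger receptor gene Scarb1, 1 and 2 at Vav1 and 0 and 1 at C1qc. Among antigen presentation genes it was 11 of 19 (3.22, 0.0013), with 3 and 0 at the cathepsin gene Ctss, 2 and 0 at Cd74 and at Cd86, 1 and 2 at Ciita and 0 and 1 at Psmb9. Among genes of Toll-like receptor and NF-kB signalling it was 14 of 22 (5.36, 0.0019), with 4 and 0 at Tab2, 4 and 3 at Tnfaip3, a negative regulator of NF-kB, 2 and 0 at Irak2 and 0 and 1 at Nfkbiz. Among JAK-STAT genes it was 13 of 22 (5.41, 0.0051), with 6 and 0 at Ifngr1, a chain of the interferon-gamma receptor, 3 and 0 at Stat5b, 2 and 0 at Ifnar1 and 0 and 1 at Socs2 and at Stat4. The Ifngr1 peaks lay 21508 to 99969 bp from the gene's end. The Tab2 peaks were all intergenic, 4203 to 99196 bp from an end of the gene, and the Nfkbiz peak lay 53937 bp away. With assignment limited to 10 kb the JAK-STAT list no longer passed, with 8 members against a random mean of 3.41 (permutation, adjusted p = 0.061).

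Transcription factor genes of the microglial lineage carried peaks of both genotypes. A cKO-specific peak was found at 16 of 24 (random mean 7.07, permutation, adjusted p = 0.0030) and a cWT-specific peak at 15 of 24 (4.17, 0.0038); this was the only one of 19 lists that passed in the cWT list. Runx1 had 7 cKO-specific and 1 cWT-specific peaks, Smad3 6 and 2, Irf8 6 and 3, Mef2c 3 and 3, and Tcf4 2 and 3. With a limit of 10 kb the list still passed in cWT and no longer in cKO, where 8 members stood against a random mean of 3.76 (permutation, adjusted p = 0.087).

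AP-1 and other bZIP factor genes had a cKO-specific peak at 12 of 22 members (random mean 5.29, permutation, adjusted p = 0.0059). Jdp2, which encodes a Jun dimerization partner, had 4 cKO-specific and 0 cWT-specific peaks: 1 lay 294 bp from an end of the gene (chromosome 12, 85598042 to 85598682, signal 22.7, p-value 0.575), 1 inside it (85629804 to 85630158), and 2 in the intergenic stretch beyond its other end (85648348 to 85648543 and 85659401 to 85659600). Bach2 had 7 cKO-specific and 3 cWT-specific peaks, Bach1 4 and 1, and Maf 2 and 2. Inflammatory cytokine and mediator genes had a cKO-specific peak at 12 of 24 members (5.04, 0.0059), with 2 each at Cxcl2, Il18 and Il1b and, at Il6, 2 in each list; Il12b had 1 cWT-specific peak and 0 cKO-specific peaks. Genes of disease-associated microglia had one at 14 of 27 members (5.95, 0.0059); Cd9 had 4 cKO-specific and 2 cWT-specific peaks, Cd63 and Ch25h 1 and 0 each, and Ctsl 0 and 2. With a limit of 10 kb the bZIP list (7 members against 3.11, permutation, adjusted p = 0.087) and the disease-associated list (9 against 3.81, 0.061) no longer passed in cKO.

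**Figure D2:**
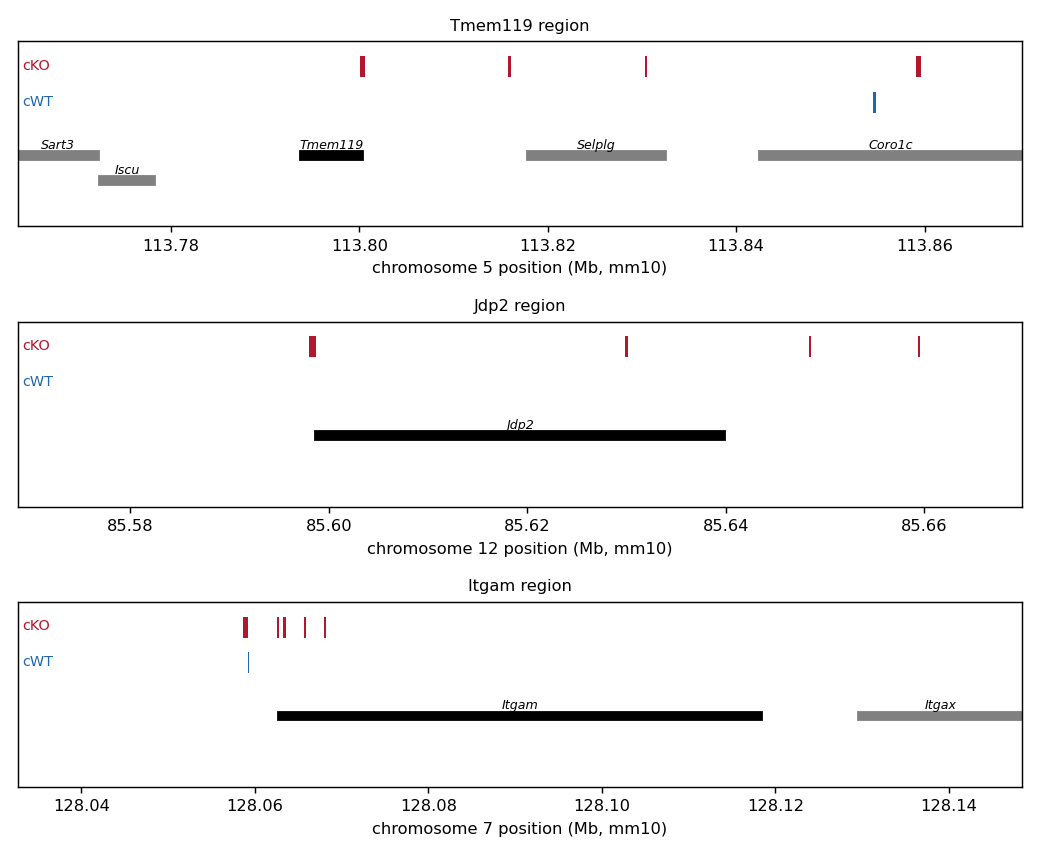
Genotype-specific peaks (cKO red, cWT blue; drawn to scale) and protein-coding gene spans (black for the named gene, grey for others) around Tmem119, Jdp2 and Itgam, by chromosome position in Mb of mm10. A cKO-specific peak lies at an end of Tmem119, Jdp2 has 4 cKO-specific peaks and 0 cWT-specific peaks, and Itgam has 5 cKO-specific peaks beside 1 cWT-specific peak.

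The remaining lists did not pass in either genotype. Interferon response genes had a cKO-specific peak at 5 of 21 coding members (permutation, adjusted p = 0.702): Irf1 had 3 and 0, Ddx58 2 and 1, Irf9 1 and 0, and Oasl2 0 and 1. Lipid and cholesterol genes had one at 9 of 22 (0.250), with 5 and 1 peaks at the sterol transporter gene Abcg1, 4 and 0 at Abca1 and at Lrp1, 1 and 3 at Npc2, and 0 and 2 at Pparg. Cell cycle genes had one at 8 of 22 (0.250), with 8 and 1 at Cdk6, 4 and 0 at Ccnd2, 4 and 1 at Aurkb and 3 and 2 at Ccnd1, and a cWT-specific peak at 7 of 22 (0.084). Genes reported as miR-137 targets had a cKO-specific peak at 5 of 18, against a random mean of 5.64 (0.955), and a cWT-specific peak at 6 of 18 (3.55, 0.478); Cdk6 and Tcf4 are also on other lists, Cdc42 had 2 and 1, and Grin2a 0 and 1.

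No list of markers of other brain and blood cells passed in either genotype, the lowest adjusted p in cWT being 0.403. A cKO-specific peak was assigned to 4 of 22 neuronal genes (permutation, adjusted p = 0.587), 6 of 15 astrocyte genes (0.492), 5 of 16 genes of the oligodendrocyte lineage (0.766), 7 of 15 vascular genes (0.286), 7 of 16 genes of other macrophages and monocytes (0.165) and 2 of 18 lymphocyte genes (0.587). Examples were 5 cKO-specific and 1 cWT-specific peaks at Celf4, 4 and 2 at Slc1a3, 3 and 1 at Mbp, 3 and 0 at Stmn2, Pecam1, Acta2, Hpgds and Plac8, 2 and 2 at Kdr, 2 and 1 at Cd4, 1 and 2 at Flt1 and 0 and 2 at Id4.

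A difference between the genotypes was tested on the balance of peaks, and no gene list passed. Homeostatic genes had 36 cKO-specific and 8 cWT-specific peaks, an odds ratio against all other assigned peaks of 1.78 (0.811 to 4.43). JAK-STAT genes had 27 and 5 (2.13, 0.809 to 7.098), antigen presentation genes 17 and 3 (2.24, 0.646 to 11.9) and lineage factor genes 44 and 25 (0.692, 0.414 to 1.18). By Fisher's exact test 0 of 19 lists passed, and 0 had an unadjusted p under 0.05; the lowest adjusted p was 0.941. Passing the coverage test in cKO and not in cWT is therefore not shown to be a difference between them. For single genes, 0 of 270 with at least 5 peaks passed the exact binomial test of their cKO share, and 6 had an unadjusted p under 0.05: Cyria, Dhrs3, Gm1966, Man1a2, Wwp2 and Zcchc24, each with 1 cKO-specific and 4 cWT-specific peaks (exact p = 0.0247). In simulated data with 200 of the 270 genes shifted at once, this test recovered 85.0% of those shifted to 5% cKO peaks. It recovered 0 of 200 shifted to 98%, so it could not show a gene moved towards cKO. The adjustment is milder when so many genes are shifted, so the 85.0% does not hold for a few genes moved towards cWT.

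**Figure D3:**
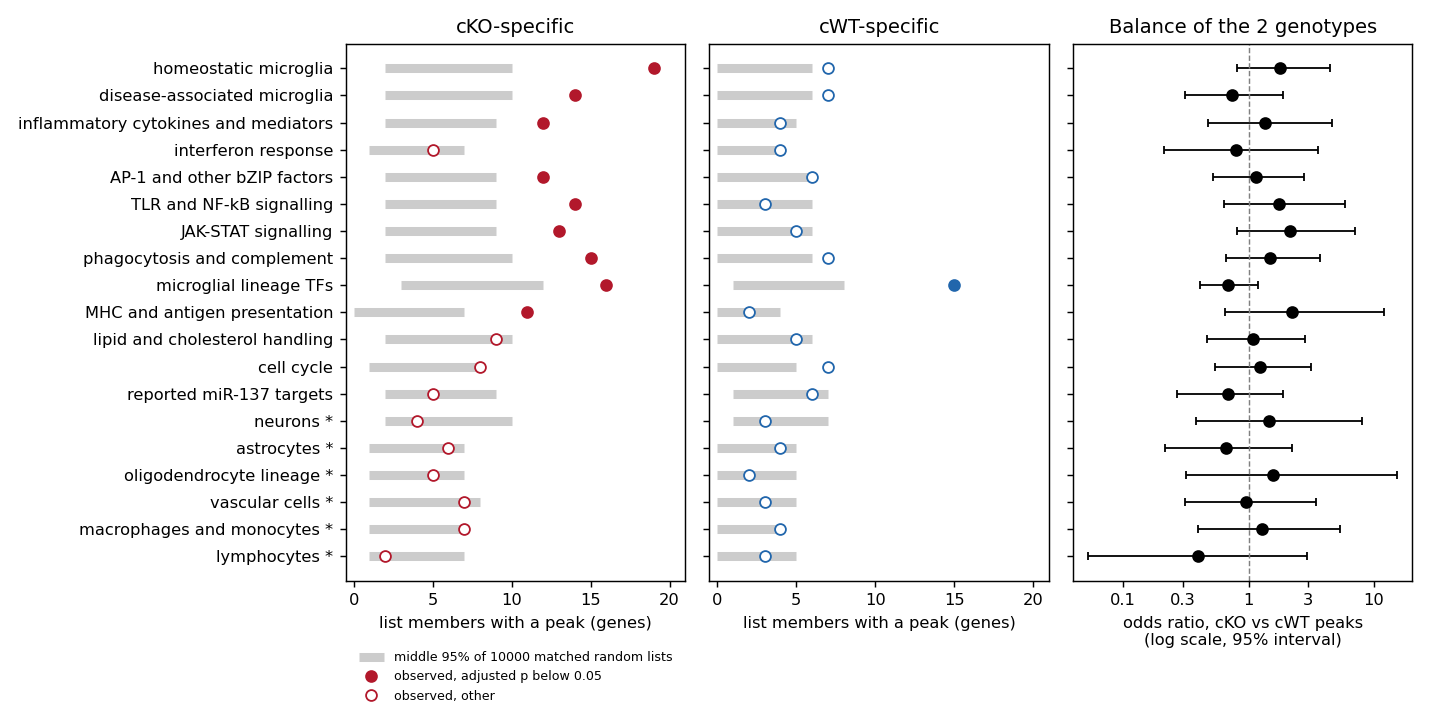
Left and centre, members of each of 19 gene lists with at least 1 cKO-specific (red) or cWT-specific (blue) peak, filled where the adjusted p is below 0.05, over the middle 95% of 10000 matched random lists (grey); an asterisk marks lists of other cell types. Right, odds ratio of cKO-specific against cWT-specific peaks with its 95% interval on a log scale. By coverage 9 lists pass in cKO and 1 in cWT, and 0 of 19 pass the test of balance between the genotypes.

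The specific peaks lay mostly away from gene ends in both genotypes, and cKO-specific peaks lay there less often. Within 1000 bp of either end of a protein-coding gene there were 1182 cKO-specific peaks (13.7%) and 554 cWT-specific peaks (15.9%), an odds ratio of 0.843 (Fisher's exact test, 0.754 to 0.942, adjusted p = 0.0072; block bootstrap interval 0.754 to 0.940). Gene interiors held 51.2% and 49.3% (odds ratio 1.08, Fisher's exact test, adjusted p = 0.085) and intergenic stretches 35.1% and 34.8% (1.01, 0.817). Among peaks with p-values up to 0.5 the gene-end shares were 26.3% and 37.7%, an odds ratio of 0.590, and within 3000 bp 36.6% and 50.2%, an odds ratio of 0.571. Over all peaks the gene-end difference was lost with a window of 3000 bp (odds ratio 0.952, exact p = 0.302) and among peaks at or above the median score of their list (0.879, exact p = 0.092). The median distance to the nearest coding gene end was 12412 bp in cKO and 15635.5 bp in cWT (difference of medians -0.100 on the log10 scale, permutation p = 1e-05, the smallest that 100000 resamples can give), but with all annotated genes it was 6548 and 6662 bp (-0.0075, p = 0.654).

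Chromosomes 11 and 18 departed from the genome-wide balance in opposite directions. Chromosome 11 held 722 cKO-specific and 218 cWT-specific peaks (odds ratio 1.37, 1.17 to 1.61, Fisher's exact test, adjusted p = 0.0012), and chromosome 18 230 and 129 (0.715, 0.571 to 0.897, adjusted p = 0.031). Among peaks at or above the median score the chromosome 18 difference was no longer past the threshold (0.708, Fisher's exact test, adjusted p = 0.211). On chromosome 11 the 4 blocks of 10 Mb from 0 to 40 Mb were 55.6% to 64.8% cKO, and the 9 blocks beyond 40 Mb 73.8% to 81.9%, against 71.2% for the genome. The X chromosome held 152 and 55 peaks (1.12, 0.817 to 1.56), and neither list had a peak on Y.

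**Figure D4:**
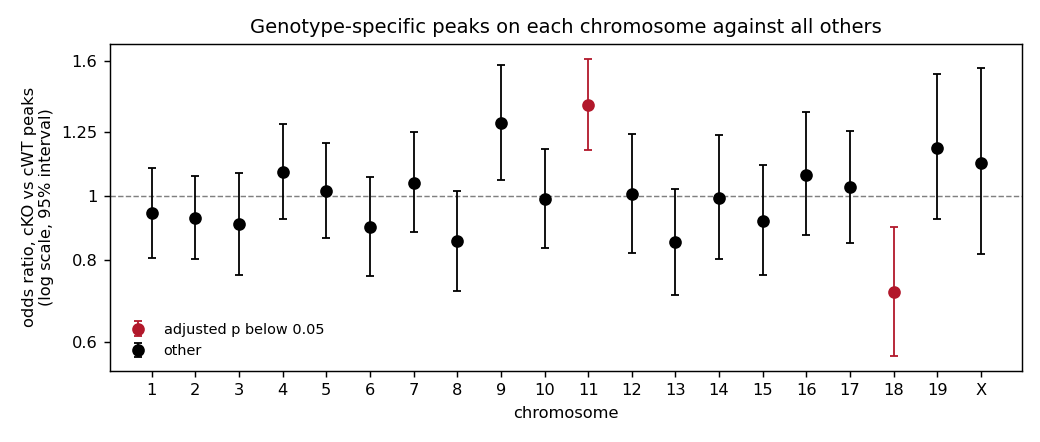
Odds ratio of cKO-specific against cWT-specific peaks on each chromosome compared with all others (log scale), with 95% intervals over peaks; red marks an adjusted p below 0.05. Chromosome 11 lies above 1 (1.37) and chromosome 18 below it (0.715).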

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

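Chosen after the results were seen were the settings on the authors' p-value, the primary peaks, the numbered peaks, the 500 bp gene-end window, chromosome 11 without its top block, and both comparisons of list members. No paired analysis was possible because the lists hold no values per library; leaving out replicates, the replicate block, and the planned motif, GC and exon alternatives were not run. Of 47 alternatives, 28 kept direction and side of the threshold or, for counts and the peak ratio, stayed close to the main value. Restriction to standard chromosomes could change nothing, because every listed peak lay on them. Among peaks at or above the median score of their list, the upper part by score below, 4332 cKO-specific and 1792 cWT-specific peaks remained by construction; 1042 and 215 had p-values up to 0.5 (ratio 4.85), 243 and 48 were primary (5.06), and per numbered peak the ratio was 2.13. The overlap was 0 peaks when 50% of the shorter peak had to be shared and 376 within 500 bp, also by construction. The gene-end odds ratio lost its call at 3000 bp (0.952) and in the upper part by score (0.879), where the intergenic odds ratio turned to 0.971; the distance difference lost it with all annotated genes (-0.0075). The cause was not tested. With a 10 kb limit 5 rather than 9 lists passed for cKO: homeostatic, inflammatory, Toll-like receptor and NF-kB, phagocytosis, and antigen presentation. The 4 others had 7 to 9 members with a peak against random means of 3.11 to 3.81, and fewer peaks were counted by construction. In the upper part by score 1 chromosome passed, chromosome 11 (odds ratio 1.54), and chromosome 18 did not (0.708, Fisher's exact test, adjusted p = 0.211).

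List balance stayed at 0 lists under a 10 kb limit, no limit, assignment to the enclosing gene, and the upper part by score. Counting list members in place of peaks, with the cKO list thinned at random to 3490 peaks, gave 2 lists: miR-137 targets (6 members in cWT against a median of 3 in thinned cKO lists) and lymphocyte genes (3 against 1). Both had an adjusted p of 0.019 over the random draws. That comparison leaves out the sampling error of the cWT list: in simulated data with no difference it gave an unadjusted p under 0.05 for 11.1% of lists. It was therefore replaced, after its result was seen, by permuting the genotype labels over all peaks, which gave 2.42% in the same simulation; by that permutation test 0 of 19 lists passed and 0 had an unadjusted p under 0.05, with adjusted p = 0.883 for miR-137 targets.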

Other observations

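The tests of the cKO excess below were chosen after the result was seen; those of chromosome 11 and of neighbouring peaks were written before their results. The strata of gene density were redrawn once, because tied values had first been split in an order that followed genotype.

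Runs of specific peaks with consecutive numbers were looked for after the data were seen. With 25.8% of numbered cKO peaks specific, random placement also gives some runs. How many of each length it gives was not worked out, so the runs below are only described. The longest runs of consecutive numbered cKO peaks that were all specific held 7 peaks each, 1 over 131 kb at Rad51b on chromosome 12 (79754854 to 79885665), where a cWT run of 4 also lay (79755142 to 79983699), and 1 over 277 kb on chromosome 9 (48559676 to 48836486) at Zbtb16, a zinc finger transcription factor gene, and Nnmt, the nicotinamide N-methyltransferase gene. The most compact run of 6 lay within 20.8 kb at Tmem44 on chromosome 16, and another run of 6 lay at Hoxc8, Hoxc9, Hoxc10 and Calcoco1 on chromosome 15. Runs of 5 included Itgam, Smad3 with Aagab, and Ctsc, a cathepsin gene, with Grm5. In cWT the longest runs held 5 peaks, among them Smyd3 with Kif26b on chromosome 1 and Psd3 with Sh2d4a on chromosome 8.

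The share of cKO-specific peaks differed with gene density. With 0 to 3 coding genes within 500 kb, 65.6% of specific peaks were cKO-specific, with 23 to 31 genes 77.1%, and with 32 to 72 genes 74.96%; the median number of genes was 11 for cKO-specific and 10 for cWT-specific peaks (permutation p = 0.0246).

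The excess of cKO-specific peaks was weighed against 2 technical explanations. Peaks near the calling limit stay open: the ratio was 4.85 at p-values up to 0.5, above the 2.47 of all peaks, but 1.75 (0.445 to 8.15) at p-values up to 0.05, from 7 and 4 peaks, and what the p-value tests is not stated. A longer called list in cKO, as deeper or cleaner libraries could give, stays open: the cKO numbering ended 4592 higher than the cWT numbering, near the difference of 5125 specific peaks, and depth is unknown. Genotype and list length cannot be told apart here, and the effect of losing miR-137 stays open, untested against the spread between animals.

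The balance of chromosome 11 was weighed against gene density and a single region. Within 10 strata of gene density the odds ratio was 1.23 (1.05 to 1.44) against 1.37 without strata, so density may account for part of it. Whether it accounts for all of it is not decided, because only the count of coding genes within 500 kb was used, in coarse strata. Without the 10 Mb block of largest cKO excess it was 1.33 (1.12 to 1.58), so a single block was not the whole cause. The intervals treat peaks as independent, so they may be too narrow. A regional difference between the genotypes remains a hypothesis, and a difference in library quality that acts on parts of chromosomes was not tested.

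Specific peaks neighboured each other more often than random placement gave. In cKO 2477 pairs had consecutive numbers, above the highest of 10000 placements within each chromosome (2375, mean 2238), and in cWT 567 against a highest of 495, so a rise over whole chromosomes was not enough. Split or adjoining peaks stay open: 1935 of the cKO pairs lay at least 1000 bp apart, below 2375, but the placements count close pairs too, because positions of the unlisted peaks were not used, so that comparison does not decide.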
